A study of Mauremys reevesii with 9 samples.

How the data were processed

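Reeves' turtle (Mauremys reevesii) is a freshwater turtle whose sex follows the temperature of the egg. RNA was taken from complexes of adrenal, kidney and gonad dissected together at Greenbaum stage 16. Per the labels, eggs were held at 26 °C (male-biased), 29 °C (mixed sex) or 32 °C (female-biased), with 3 replicates at each temperature and 9 libraries in all. The labels do not say whether a replicate was 1 embryo or a pool, nor from which clutch it came. P-values therefore measure the spread between these samples, which may be technical.

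The authors deposited, for each library, an expected count per assembled gene, an estimated read number that need not be whole. Between 0.50% and 0.59% of the values in a library were not whole numbers. The authors also deposited an FPKM for every gene, which divides the count by the gene's length and the library's depth. RSEM and DESeq version 1.10.1 are named in the submitters' processing notes. The assembler, the aligner and any genome build are not given in the sources used here. The gene identifiers have the form of a de novo assembly, and none of them (0 IDs) matched the reference gene table, so no coordinates are given. A gene of the animal can be split over several assembled genes, and reads of near-identical copies can be shared between them.

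A further deposited table held 870 assembled genes that the authors called in at least 1 comparison. It gives the authors' log2 ratio and the authors' q-value for each comparison. In the authors' deposited table the highest q-value of a called gene was 0.0497 and the lowest of a gene not called was 0.0502. The counts in that table did not differ from those of the library files in any value (0 values differed).

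Names came from this table alone: the symbol in the best nucleotide hit (327 genes), else the Swiss-Prot hit (104 genes), else the product name (40 genes). That named 471 of the 870 genes with 432 distinct names, and 399 stayed unnamed. Where both hits gave a symbol (240 genes), they gave the same one for 222. Names are those of the best hit in other vertebrates and were not checked by sequence. A gene outside the authors' table has no name here, so any count of named genes is a count among genes the authors had already picked on these libraries.

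Expected counts were rounded to whole numbers. Of 551078 assembled genes listed, 101058 had no count in any library. Genes were filtered with filterByExpr by temperature, which left 58462 genes holding between 97.7% and 98.1% of each library's reads. Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with all 9 libraries in 1 quasi-likelihood model, temperature as the only term and 6 residual degrees of freedom. The 3 pairs of temperatures were tested as contrasts, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05, without a fold limit. The biological coefficient of variation was 18.6%. A standard error is the size of the log2 fold change divided by the square root of its F statistic. CPM is the cpm unit of edgeR, counts relative to TMM-scaled library size, given as mean ± SD over n = 3.

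The depth ran from 17606579 to 25124901 counts per library, and the 32 °C libraries were the deepest. A count of 3 in a library was taken as the floor of detection. Counting intervals have a level of 95% (Clopper-Pearson, from the share of the summed counts) and cover counting error only.

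The rule for the genes to name was fixed before the data were examined, and the genes themselves were picked by their values in these libraries. They had an adjusted p under 0.05, a name, a mean of at least 1 CPM over all libraries and libraries of the compared temperatures that did not overlap, which chance alone gives for 10% of genes. The 10 highest and 10 lowest log2 fold changes were taken for 32 °C against 26 °C, and the 5 highest and 5 lowest for each of the other comparisons. Uncharacterized, hypothetical and transposon proteins were left out. Of a symbol carried by several assembled genes, the one with the highest mean CPM was used. Members of 22 gene lists, also fixed in advance, could be named as well: every member of the testis, ovary, temperature and calcium sensing, and heat shock lists, and up to 5 of each other list by smallest p. The lists hold 429 distinct symbols, of which 30 are named in the authors' table. Adjustment over the list alone covers only these named members, which the authors had called on the same libraries, and with 1 member it is the unadjusted p. The planned set test (camera) needs names for genes whether or not they were called, so it was not run and counts of members are given.

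The procedure was tested on simulated data drawn from the means, depths and dispersions of the 58462 genes. The changed genes were taken among those with a mean of at least 1 CPM, so recovery at lower levels was not measured. They were 100 changed 2-fold and 100 changed 4-fold, far fewer than the 2003 genes called in the data at 32 against 26 °C. The adjusted threshold depends on how many genes differ, so recovery and false share need not carry over to those calls. For 32 °C against 26 °C, edgeR recovered 40 of 100 genes changed 2-fold and 91 of 100 changed 4-fold, with 14 false calls among 145. For 32 °C against 29 °C it recovered 40 of 100 and 94 of 100, with 15 false among 149. For 29 °C against 26 °C, simulated with no change, it made 1 call. In the 2 changed comparisons the false share of the edgeR calls was above the threshold of 0.05. Under the same conditions DESeq2 made 10 calls in the unchanged comparison and 38 false among 178 for 32 °C against 26 °C. It recovered 48 and 92 of 100 genes for 32 °C against 26 °C. For 32 °C against 29 °C it recovered 54 and 96, with 42 false among 192. Limma on log2(CPM + 1) recovered 39 and 90 of 100 for 32 °C against 26 °C, with 13 false among 142. FPKM and the fit without a low-count filter were not simulated.

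Alternatives set before the data were examined were RLE size factors, DESeq2 1.42.0, no filter beyond 1 count in any library, a filter of 1 CPM in 3 libraries, only the 6 libraries compared, a replicate block, limma 3.58.1 on log2(FPKM + 1) and on log2(FPKM + 0.1), a 2-fold minimum, summing the assembled genes of a symbol, and leaving out each library in turn. Thinning all libraries to the smallest total of rounded counts, 17606572, was added after seeing the data.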

Results

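The transcriptomes of adrenal-kidney-gonad complexes from Reeves' turtle embryos were compared between incubation at 26, 29 and 32 °C, with 3 libraries at each temperature. The complex holds the future gonad together with the neighbouring kidney and adrenal tissue, and all libraries were of stage 16. The library totals at 26 °C were 18159185, 17606579 and 17821117 counts, at 29 °C 18136366, 18618687 and 18609992, and at 32 °C 25124901, 19815660 and 20457455. No pair of replicates held identical values, and each pair differed by more than sampling noise, with a chi-square per degree of freedom between 3.93 and 9.78. On the first principal component, which took 27.6% of the variance, the 26 °C libraries lay at -44.9, -46.1 and -60.3 and the 32 °C libraries at 62.9, 104.9 and 59.2. The 29 °C libraries lay at 2.6, -43.8 and -34.3, so replicate 1 at 29 °C stood nearer to the 32 °C side than the other two. Per the labels, the study looked for genes tied to temperature-dependent sex determination.

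The first comparison asked what differs between the female-biased and the male-biased temperature. At 32 °C, transcripts of anti-Müllerian hormone (AMH, c281848_g1), which drives regression of the Müllerian ducts in males, fell 61.8-fold, from 137 ± 55.5 CPM at 26 °C to 2.22 ± 0.535 CPM (SD, n = 3 each). The log2 fold change was -5.95 ± 0.32 (SE, edgeR adjusted p = 3.7e-06). DMRT1 (c257698_g2), a transcription factor of the male pathway, fell from 2.80 ± 0.552 to 0.181 ± 0.0709 CPM, a log2 fold change of -3.87 ± 0.36 (edgeR adjusted p = 0.000267). It rested on 12 counts over the 32 °C libraries against 145 at 26 °C. NR5A1 and LHX9, transcription factors of the early gonad, fell by about as much as each other, with log2 fold changes of -1.11 ± 0.16 and -1.04 ± 0.15 (edgeR adjusted p = 0.00422 for both). These were the 4 members of the testis list of 22 named in the authors' table. All 4 were lower at 32 °C, and all 4 also passed when adjusted over the list alone. Since the authors picked these genes on the same libraries, neither count is independent evidence of a direction for the list. With limma on FPKM, the call of LHX9 ended at an adjusted p of 0.0546.

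**Figure D1:**
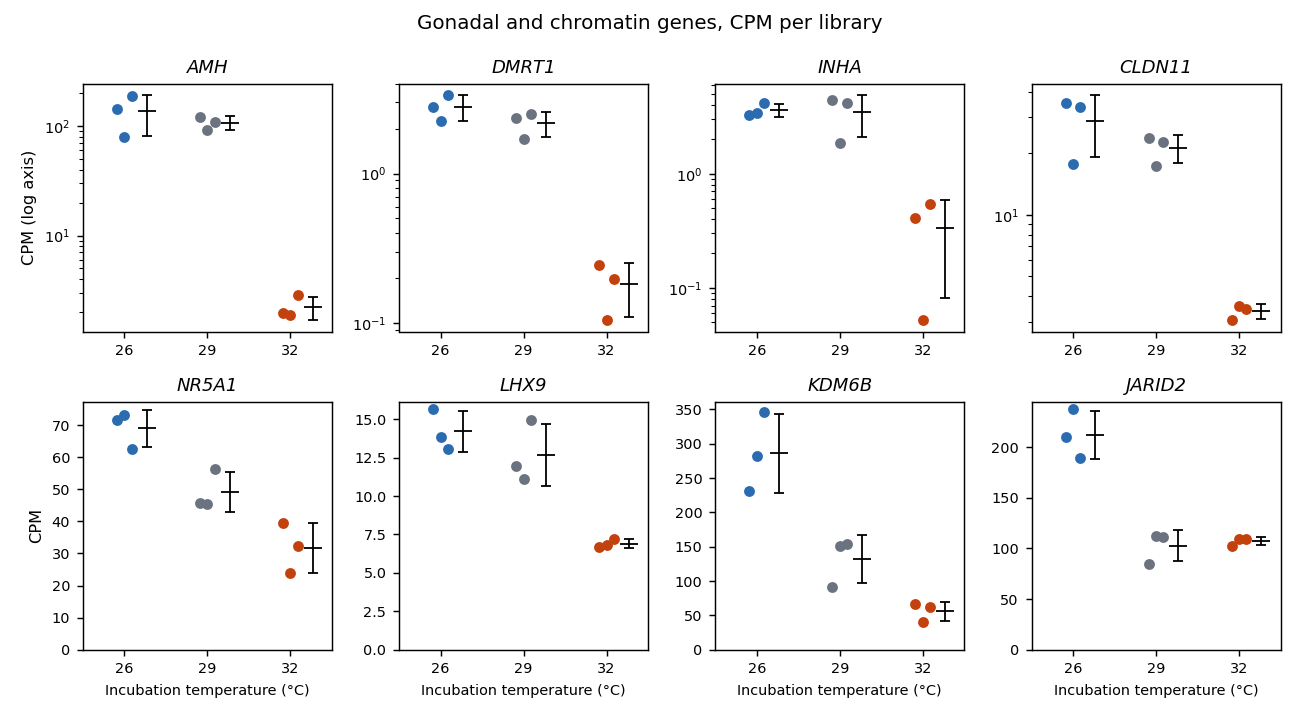
CPM of AMH, DMRT1, INHA, CLDN11, NR5A1, LHX9, KDM6B and JARID2 against incubation temperature in °C. Each point is a library, bars are mean ± SD over 3 libraries, the upper row has log axes and the lower row starts at 0. AMH lies between 1.87 and 2.83 CPM in the 32 °C libraries and between 78.7 and 189 CPM at 26 °C.

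INHA, CLDN11, TGFBR3L, CRABP1, IL23R, MYBPC1 and MYH3 were also among the 10 lowest log2 fold changes of named genes at 32 °C. INHA, the alpha subunit of inhibin, fell by 3.39 on the log2 scale, from 3.61 ± 0.504 to 0.332 ± 0.251 CPM (edgeR adjusted p = 0.00344). CLDN11, a tight junction protein of Sertoli cells and of myelin, fell by 3.11, from 29.0 ± 9.72 to 3.37 ± 0.286 CPM (edgeR adjusted p = 0.000114). TGFBR3L, named for its likeness to the type III receptor of transforming growth factor beta, fell by 3.20 with an SE of 0.38. CRABP1, which binds retinoic acid in the cytoplasm, fell by 2.60 with an SE of 0.32. IL23R, the interleukin 23 receptor, fell by 3.65, from 6.42 ± 0.811 to 0.492 ± 0.309 CPM. A second assembled gene with the same name, c241551_g1, fell by 4.83 with an SE of 0.61. The muscle genes MYBPC1 and MYH3 had log2 fold changes of -2.94 and -2.48, and that of MYH3 was -1.65 without replicate 2 at 26 °C. That of IL23R was -4.26 without replicate 1 at 32 °C. MYH3, the 1 muscle list member named, lost its call in 4 of the 9 fits that left out a library, with adjusted p between 0.0539 (without replicate 2 at 32 °C) and 0.0799 (without replicate 2 at 26 °C), the others being replicates 1 and 3 at 32 °C.

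In the ovary list of 20, the 2 members named in the authors' table went opposite ways, and both passed when adjusted over the list alone. IRX5, a homeobox factor, rose from 2.72 ± 0.406 to 6.92 ± 0.765 CPM, a log2 fold change of 1.34 ± 0.22 (edgeR adjusted p = 0.00915). HSD17B1, an enzyme that converts estrone to estradiol, was lower by 0.82 with an SE of 0.20 (edgeR adjusted p = 0.0376). Its call ended on leaving out any 1 of the 26 °C or 32 °C libraries, with adjusted p between 0.0554 (without replicate 1 at 26 °C) and 0.137 (without replicate 3 at 26 °C). With limma on FPKM, neither passed: adjusted p reached 0.223 for IRX5 and 0.324 for HSD17B1.

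The chromatin list of 26 had 2 members named, and both were lower at 32 °C and passed when adjusted over the list alone. KDM6B (c281448_g1), a demethylase of lysine 27 of histone H3, fell from 286 ± 57.6 to 56.0 ± 14.0 CPM, a log2 fold change of -2.35 ± 0.23 (edgeR adjusted p = 4e-04). The name KDM6B stood on 4 assembled genes, and all 4 were lower, with log2 fold changes of -2.59, -2.35, -2.08 and -1.98. JARID2 (c275221_g6), a partner of Polycomb repressive complex 2, fell from 212 ± 23.9 to 107 ± 3.88 CPM, a log2 fold change of -0.99 ± 0.12 (edgeR adjusted p = 0.00176).

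In the heat shock list of 37, the 4 members named in the authors' table, all higher at 32 °C and all passing when adjusted over the list alone, were HSP90AA1, DNAJA4, SERPINH1 and HSPH1. HSP90AA1, a cytosolic chaperone, rose from 196 ± 9.06 to 482 ± 96.5 CPM, a log2 fold change of 1.30 ± 0.13 (edgeR adjusted p = 0.000534). SERPINH1, a chaperone of collagen, rose by 1.01 ± 0.10, DNAJA4 by 1.04 ± 0.15 and HSPH1 by 0.96 ± 0.12. Reads of near-identical chaperone genes could be shared in the counting. In the temperature and calcium sensing list of 20, CIRBP and TRPM8 were named, both higher, and both passed when adjusted over the list alone. CIRBP, known as a cold-inducible RNA-binding protein, rose from 550 ± 21.2 to 870 ± 48.2 CPM, a log2 fold change of 0.66 ± 0.08 (edgeR adjusted p = 0.00225). TRPM8, a cold-activated ion channel, rose by 0.76 ± 0.18 (edgeR adjusted p = 0.0402). Its call ended without replicate 1 or 2 at 26 °C, replicate 2 at 29 °C or any 32 °C library, with adjusted p between 0.0519 (without replicate 2 at 29 °C) and 0.135 (without replicate 1 at 26 °C), and with limma on FPKM at 0.112.

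Some named markers of other cell types in the complex also differed. The 4 red blood cell genes named from a list of 19 were lower at 32 °C, and all 4 passed when adjusted over the list alone. HEMGN, a nuclear protein of blood progenitors, fell by 1.09 with an SE of 0.13 (edgeR adjusted p = 0.00176). The globins HBAA and HBAD and the anion exchanger SLC4A1 fell by 0.67, 0.65 and 0.72. HBAA dropped from 2429 ± 436 to 1529 ± 349 CPM, and globin copies can share reads. The calls of these 3 genes ended without replicate 2 or 3 at 26 °C or replicate 2 at 32 °C, with adjusted p up to 0.146 for HBAA, 0.109 for HBAD and 0.117 for SLC4A1, each without replicate 3 at 26 °C. Those of HBAA and HBAD also ended without replicate 3 at 32 °C (0.108 and 0.088), and that of HBAA without replicate 1 or 2 at 29 °C (0.0503 and 0.0521). These 3 reached adjusted p of 0.182, 0.123 and 0.113 with limma on FPKM. In the adrenal cortex list of 16, CYP21A2, the steroid 21-hydroxylase, was lower by 1.45 with an SE of 0.31 (edgeR adjusted p = 0.0246), from 80.9 ± 13.3 to 29.5 ± 16.1 CPM. Its call ended without replicate 2 or 3 at 26 °C or replicate 3 at 32 °C, at adjusted p of 0.0654, 0.0829 and 0.083.

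In the kidney list of 22, PAX2 was higher (0.85 ± 0.15) and PAX8 lower (-0.79 ± 0.17), both being transcription factors of the developing nephron. PAX2 lost its call without replicate 1 or 2 at 26 °C (0.0514 and 0.0569). PAX8 lost it without any 26 °C library or replicate 2 or 3 at 32 °C, with adjusted p from 0.0548 (without replicate 1 at 26 °C) to 0.0854 (without replicate 3 at 26 °C). The neuronal genes GAP43 and STMN3 of a list of 12 were higher by 0.83 ± 0.14 and 0.86 ± 0.20. STMN3 lost its call without replicate 1 or 2 at 26 °C or any 32 °C library, with adjusted p from 0.0687 (without replicate 1 at 32 °C) to 0.114 (without replicate 1 at 26 °C). Both members of the kidney list and both of the neuron list passed when adjusted over the list alone.

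The remaining lists had 1 or 2 named members each. PER1, a clock gene, fell by 1.46 with an SE of 0.21 (edgeR adjusted p = 0.00443). SOD3, an extracellular superoxide dismutase, was lower by 0.72 and lost its call without any 26 °C library or replicate 1 or 3 at 32 °C, with adjusted p from 0.0539 (without replicate 2 at 26 °C) to 0.092 (without replicate 1 at 26 °C). LAMB1, a laminin chain, was lower by 1.40 and lost it without replicate 1 or 2 at 26 °C (0.0529 and 0.0565). COL9A1 of the same matrix list had a log2 fold change of -0.79 ± 0.37 and did not pass (edgeR adjusted p = 0.257). The germ cell gene MAEL had a log2 fold change of 1.80 ± 0.47 and did not pass (edgeR adjusted p = 0.0558). CHGB, of the chromaffin list, had 0.64 ± 0.22 and did not pass (edgeR adjusted p = 0.123). The calls of MYH3, CYP21A2, PAX2, PAX8, STMN3, SOD3 and LAMB1 also ended with limma on FPKM, with adjusted p up to 0.143, 0.0727, 0.062, 0.111, 0.104, 0.0761 and 0.0712. MAEL passed with DESeq2 (0.00767), without a low-count filter (6.07e-06), in the fit to 6 libraries (0.0396) and without replicate 1 at 26 °C (0.0408) or replicate 1 or 3 at 29 °C (0.0468 and 0.0341). CHGB passed without a low-count filter (4.1e-05), in the fit to 6 libraries (0.0265) and without replicate 2 at 29 °C (0.0343). Of the matrix list, LAMB1 passed and COL9A1 did not when adjusted over the list alone. For a list with 1 named member this adjustment leaves the unadjusted p, which was 0.00217 for MAEL and 0.012 for CHGB, on genes the authors had picked, and it adds no evidence. No member of the immune, liver, gut and lung, cell cycle, unfolded protein response, oxidative phosphorylation or growth factor and hormone lists was among the named genes, and these were not analysed here. Over the 22 lists, 27 of the 30 named symbols passed, and without replicate 2 at 26 °C 15 did. All of them come from the genes the authors called on these libraries.

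**Figure D2:**
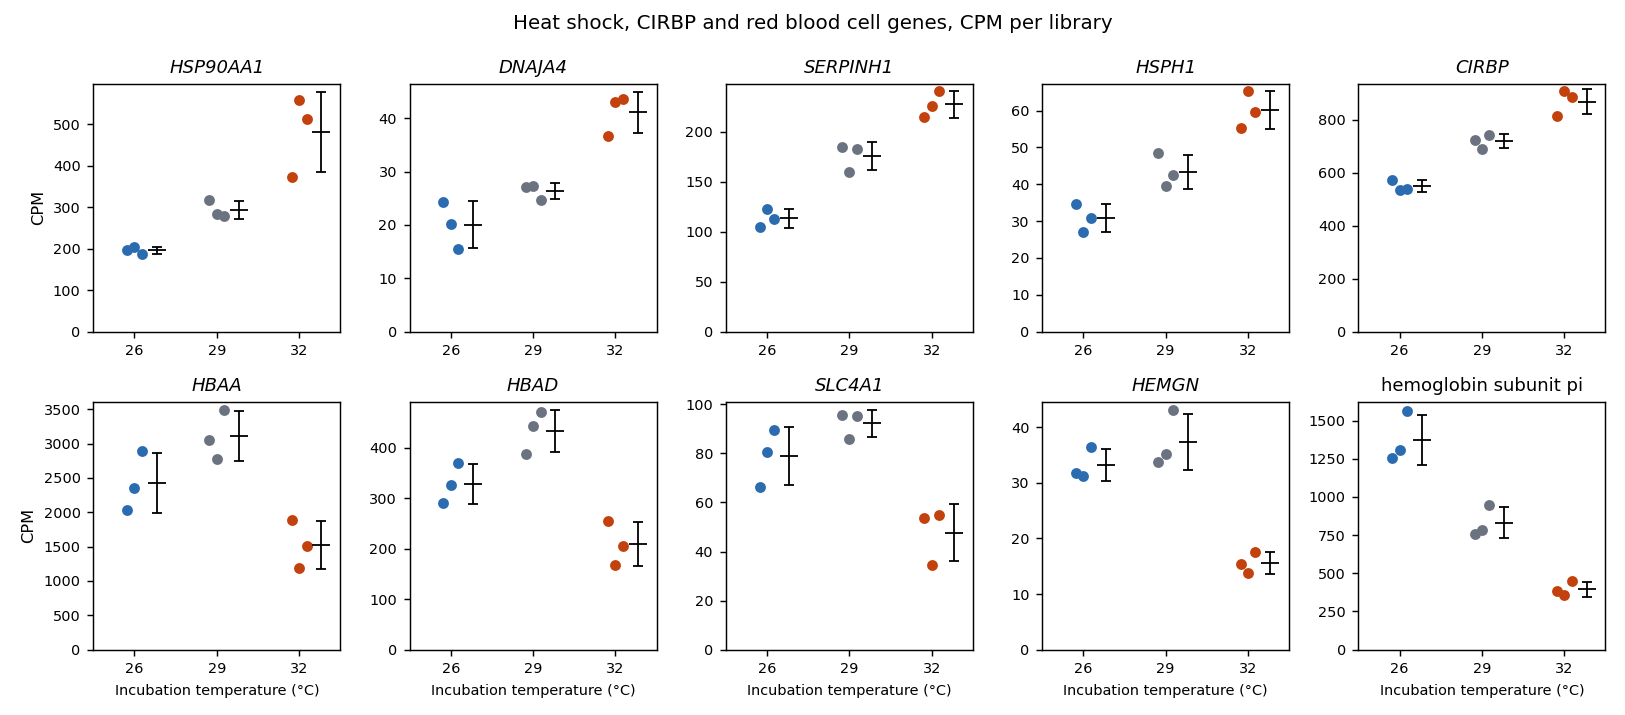
CPM of HSP90AA1, DNAJA4, SERPINH1, HSPH1, CIRBP, HBAA, HBAD, SLC4A1, HEMGN and hemoglobin subunit pi against incubation temperature in °C. Each point is a library, bars are mean ± SD over 3 libraries, and axes start at 0. HSP90AA1 has a mean of 196 CPM at 26 °C, 293 CPM at 29 °C and 482 CPM at 32 °C.

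Some of the highest log2 fold changes at 32 °C belonged to transcripts with few counts at 26 °C. MTIF3, a mitochondrial translation initiation factor, had 484 counts over the 32 °C libraries and 1 count at 26 °C, a ratio of 390 per unit of depth with a 95% counting interval of 69.6 to 15400 (edgeR adjusted p = 0.0117). CXADR, a cell adhesion protein and virus receptor, had 967 counts against 5, a ratio of 156 with an interval of 66.5 to 481 (edgeR adjusted p = 0.03). An assembled gene named USP6 N-terminal-like protein had 242 counts against 6, a ratio of 32.5 with an interval of 14.7 to 89.4 (edgeR adjusted p = 0.0411). NPDC1 and KIF20B rose by 4.92 ± 0.83 and 4.81 ± 0.72, from 23 and 17 counts at 26 °C. MTIF3, CXADR and NPDC1 stood at 2.43, 10.4 and 6.75 CPM in replicate 3 at 29 °C, and at most 0.607 CPM in replicates 1 and 2 at that temperature. TTBK2, PRSS12, a secreted serine protease, GSX2, a homeobox factor, and an interferon-inducible GTPase 5-like gene rose by 3.10 ± 0.46, 2.67 ± 0.26, 2.65 ± 0.32 and 2.63 ± 0.49. CYP2A3, a cytochrome P450, rose from 10.6 ± 3.57 to 65.0 ± 20.6 CPM. Leaving out a 26 °C library moved some fitted log2 fold changes: from 8.19 to 10.18 for MTIF3 and 4.81 to 5.48 for KIF20B without replicate 2, 4.96 to 6.72 for the USP6 N-terminal-like gene without replicate 1, and 3.10 to 3.95 for TTBK2 and 2.63 to 3.42 for the GTPase 5-like gene without replicate 3. With so few counts the fitted values of MTIF3 and the USP6 N-terminal-like gene are no bounds. Limma on FPKM moved fold sizes too: for MTIF3 the log2 fold change was 2.7 on log2(FPKM + 1) and 5.62 on log2(FPKM + 0.1). The call of MTIF3 ended without replicate 2 at 26 °C (0.0501) and that of CYP2A3 without replicate 2 or 3 at 26 °C (0.0545 and 0.0587). CXADR lost its call without any 26 °C library or replicate 1 or 2 at 32 °C, with adjusted p from 0.0535 (without replicate 1 at 32 °C) to 0.10 (without replicate 3 at 26 °C). The USP6 N-terminal-like gene lost it without any 1 of the 26 °C or 32 °C libraries, with adjusted p from 0.0534 (without replicate 3 at 32 °C) to 0.13 (without replicate 3 at 26 °C), and with DESeq2 at 0.171. With limma on FPKM, the calls of CXADR, NPDC1, CYP2A3 and the USP6 N-terminal-like gene ended, with adjusted p up to 0.0938, 0.0796, 0.0676 and 0.128. For the interferon-inducible GTPase 5-like gene limma on log2(FPKM + 0.1) ended the call (0.0649) and limma on log2(FPKM + 1) kept it (0.0343).

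**Figure D3:**
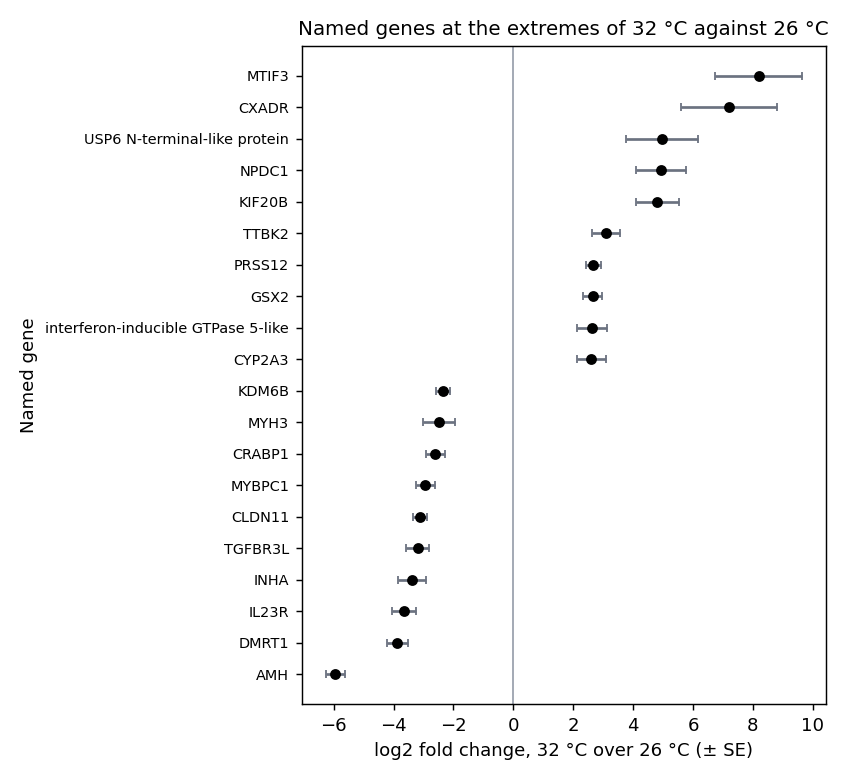
The log2 fold change of 32 °C over 26 °C for the 10 highest and 10 lowest named genes, one gene a row. Points are edgeR estimates and bars are ± SE; AMH lies at -5.95 and MTIF3, with 1 count at 26 °C, at 8.19.

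In all, 2003 of 58462 assembled genes differed between 32 and 26 °C (edgeR adjusted p under 0.05), 1022 higher and 981 lower at 32 °C, and 1133 of them by at least 2-fold. Of the 2003, 694 were in the authors' deposited table and 388 of those had a name. DESeq2 gave 3109 genes, limma on log2(FPKM + 1) 507, and the fit without a low-count filter 4043. Leaving out replicate 1, 2 or 3 at 26 °C gave 844, 711 and 723 genes, and leaving out replicate 2 or 3 at 32 °C gave 823 and 937.

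The second comparison set the mixed-sex temperature against the male-biased one. At 29 °C 9 assembled genes were lower than at 26 °C and 0 were higher (edgeR adjusted p under 0.05), while 4840 genes had an unadjusted p under 0.05. With no change at all, a share of 0.05 of the 58462 genes tested would fall under that unadjusted limit. JARID2 fell from 212 ± 23.9 to 103 ± 15.4 CPM, a log2 fold change of -1.05 ± 0.12 (edgeR adjusted p = 0.0186), which left it at about its level at 32 °C. IL23R fell by 3.97 with an SE of 0.42, from 6.42 ± 0.811 to 0.405 ± 0.251 CPM (edgeR adjusted p = 0.00998). ABCB5, an ATP-driven transporter, fell from 67.6 ± 7.76 to 26.9 ± 3.21 CPM (log2 fold change -1.33 ± 0.13). PLA2G7, the phospholipase that breaks down platelet-activating factor, fell by 0.92 with an SE of 0.12. The calls of IL23R and JARID2 ended without replicate 3 at 29 °C (0.057 for both), and that of JARID2 also without replicate 2 at 26 °C (0.0596) or replicate 2 at 29 °C (0.0573). PLA2G7 lost its call without any 1 of the 26 °C or 29 °C libraries, with adjusted p from 0.0596 (without replicate 2 at 26 °C) to 0.157 (without replicate 2 at 29 °C). With limma on FPKM, adjusted p rose to 0.159 for ABCB5, 0.20 for JARID2 and 0.24 for PLA2G7. For IL23R it was 0.111 on log2(FPKM + 0.1) and 0.007 on log2(FPKM + 1), where the call held.

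Of the genes in the lists, JARID2 alone passed at 29 °C with edgeR. The male-pathway genes AMH and DMRT1 had log2 fold changes of -0.36 ± 0.24 and -0.36 ± 0.27 against 26 °C (edgeR adjusted p = 0.758 and 0.792), NR5A1 had -0.49 ± 0.16 and LHX9 -0.16 ± 0.15. AMH stood at 107 ± 15.5 CPM. KDM6B was at 132 ± 35.0 CPM, with a log2 fold change of -1.12 ± 0.22 that did not pass (edgeR adjusted p = 0.19). HSP90AA1 had 0.58 ± 0.13, SERPINH1 0.63 ± 0.10, HSPH1 0.49 ± 0.12 and DNAJA4 0.40 ± 0.15, and CIRBP had 0.39 ± 0.08, none of which passed over all genes. IRX5 had 0.52 ± 0.23, HSD17B1 0.46 ± 0.19 and TRPM8 0.08 ± 0.19. Adjusted over the list alone, 4 of 4 heat shock genes, 2 of 2 ovary genes, 2 of 2 chromatin genes, 2 of 2 neuron genes, 2 of 2 matrix genes, 1 of 4 testis genes and 1 of 2 temperature and calcium sensing genes passed, while 0 of 4 red blood cell genes and 0 of 2 kidney genes did. The authors chose these genes on the same libraries. DESeq2 called 6 more of them, CIRBP (0.0182), HSP90AA1 (0.0259), SERPINH1 (9.38e-05), KDM6B (0.000427), GAP43 (0.000355) and LAMB1 (0.00617). Without a low-count filter 7 more passed: HSP90AA1 (0.00016), SERPINH1 (5.97e-05), KDM6B (1.14e-16), CYP21A2 (0.000916), GAP43 (2.27e-05), LAMB1 (0.000879) and PER1 (0.00288). That fit was not run on simulated counts, so its false calls are unknown. DESeq2 called 187 genes, 63 of them higher, the fit without a low-count filter 911, limma on log2(FPKM + 1) 2 and limma on log2(FPKM + 0.1) 0. Without replicate 2 at 26 °C, or replicate 2 or 3 at 29 °C, edgeR called 2, 2 and 1 genes.

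The third comparison set the female-biased temperature against the mixed-sex one. AMH fell from 107 ± 15.5 to 2.22 ± 0.535 CPM, a log2 fold change of -5.59 ± 0.31 (edgeR adjusted p = 7.18e-06), and DMRT1 fell by 3.51 with an SE of 0.36 (edgeR adjusted p = 0.0021). INHA, CRABP1 and CLDN11 had log2 fold changes of -3.34, -2.73 and -2.66 (SE 0.47, 0.32 and 0.24). LHX9 was lower by 0.88 with an SE of 0.15 (edgeR adjusted p = 0.0309), and NR5A1, at -0.63 ± 0.16, did not pass (edgeR adjusted p = 0.0999), though it did with DESeq2 (0.0186) and without a low-count filter (0.00125). So 3 of the 4 testis genes were lower over all genes tested and 4 of 4 adjusted over the list alone. The call of INHA ended without replicate 3 at 29 °C (0.0544). That of LHX9 ended without replicate 2 or 3 at 29 °C or any 32 °C library, with adjusted p from 0.0614 (without replicate 1 at 32 °C) to 0.13 (without replicate 3 at 29 °C). With limma on FPKM the calls of INHA, CRABP1 and LHX9 ended, with adjusted p up to 0.131, 0.0625 and 0.177. That of DMRT1 ended on log2(FPKM + 1) (0.0513) and held on log2(FPKM + 0.1) (0.0282).

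The 4 red blood cell genes were all lower at 32 than at 29 °C, with log2 fold changes of -1.26 for HEMGN (edgeR adjusted p = 0.0021), -1.05 for HBAD, -1.02 for HBAA and -0.95 for SLC4A1, and all 4 passed adjusted over the list alone. HBAD lost its call without replicate 2 or 3 at 29 °C or replicate 3 at 32 °C (0.0723, 0.0573 and 0.0569). HBAA and SLC4A1 lost theirs without replicate 2 or 3 at 29 °C or replicate 2 or 3 at 32 °C, with adjusted p up to 0.0897 and 0.117, each without replicate 3 at 29 °C. With limma on FPKM the calls of HBAD, HBAA and SLC4A1 ended, with adjusted p up to 0.105, 0.166 and 0.161. HSP90AA1 was higher by 0.72 ± 0.13 (edgeR adjusted p = 0.0393), KDM6B lower by 1.23 with an SE of 0.22 (edgeR adjusted p = 0.0374) and HSD17B1 lower by 1.28 with an SE of 0.19 (edgeR adjusted p = 0.0193). Each of these 3 lost its call without replicate 2 or 3 at 29 °C or replicate 2 or 3 at 32 °C, HSP90AA1 also without replicate 1 at 26 °C (0.0602), with adjusted p up to 0.17, 0.155 and 0.0945, each without replicate 2 at 29 °C. They reached 0.176, 0.212 and 0.186 with limma on FPKM. The other named heat shock genes did not pass over all genes, with log2 fold changes of 0.64 ± 0.15 for DNAJA4, 0.47 ± 0.12 for HSPH1 and 0.37 ± 0.10 for SERPINH1. Nor did IRX5 (0.82 ± 0.22), CIRBP (0.27 ± 0.08), TRPM8 (0.68 ± 0.18) or JARID2 (0.06 ± 0.12). Adjusted over the list alone, 4 of 4 heat shock genes, 2 of 2 genes each of the ovary, temperature and calcium sensing, and kidney lists, 1 of 2 chromatin and 1 of 2 matrix genes passed, and GAP43 and STMN3 did not. DESeq2 also called IRX5 (0.0374), TRPM8 (0.0265), DNAJA4 (0.00808), HSPH1 (0.0317), SERPINH1 (0.0421), PAX2 (0.0177), MAEL (0.0284), MYH3 (0.000353), COL9A1 (0.00101) and PER1 (0.0123). Without a low-count filter, IRX5 (0.0376), TRPM8 (0.000581), DNAJA4 (0.00162), CYP21A2 (2.27e-06), PAX2 (0.0437), MAEL (6.74e-05), MYH3 (1.93e-09), COL9A1 (7.97e-06) and PER1 (4.52e-06) passed too. IRX5 and TRPM8 also passed without replicate 1 at 29 °C (0.0364 and 0.0259), and MYH3 without replicate 2 at 26 °C (0.0185) and in the fit to 6 libraries (0.0287). All were genes chosen by the authors on these libraries.

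The genes with the highest log2 fold changes were expressed at low to moderate levels. TRPC2, a channel of vomeronasal sensory signalling, rose from 0.659 ± 0.195 to 3.10 ± 0.197 CPM, a log2 fold change of 2.22 ± 0.32 (edgeR adjusted p = 0.0179). GLRA3, a glycine receptor subunit, rose by 1.80 ± 0.25, ZMYM1, a zinc finger protein, by 1.80 ± 0.26, FAM170B by 1.77 ± 0.20 and SLC1A4, a transporter of neutral amino acids, by 1.66 ± 0.26. The calls of TRPC2 and SLC1A4 ended without replicate 2 or 3 at 29 °C or replicate 2 or 3 at 32 °C, with adjusted p up to 0.063 and 0.0885. Those of GLRA3 and ZMYM1 ended without replicate 3 at 29 °C (0.063 and 0.0776) or replicate 2 at 32 °C (0.055 and 0.0632). TRPC2 and ZMYM1 reached 0.173 and 0.105 with limma on FPKM. In all, 169 genes differed (edgeR adjusted p under 0.05), 94 higher and 75 lower at 32 °C, and 120 of them by at least 2-fold. DESeq2 gave 1171, limma on log2(FPKM + 1) 33 and the fit without a low-count filter 2490. Without replicate 1 at 29 °C the count was 701, without replicate 2 or 3 at 29 °C 28 and 43, and without replicate 2 or 3 at 32 °C 32 and 63.

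Of the 2003 genes that differed between 32 and 26 °C, 89.6% had a 29 °C mean between the other means, and of these 65.1% lay nearer to 26 °C on the log2 scale. For the genes higher at 32 °C, 88.6% lay between, and for those lower, 90.6%. AMH, DMRT1 and CLDN11 had 29 °C means near those at 26 °C, JARID2 near that at 32 °C, and KDM6B, HSP90AA1 and CIRBP between. The genes were picked on the outer temperatures, so these shares describe and do not test.

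The authors' deposited table lists 1011 calls over the 3 comparisons, and 776 of them (76.8%) passed here in the same comparison and direction. It was 648 of 730 for 32 against 26 °C, 8 of 42 for 29 against 26 °C and 120 of 239 for 32 against 29 °C. With DESeq2 it was 628, 36 and 196 in the same order. All calls of that table that could be tested here had the same sign as in the authors' deposited table.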

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

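Thinning of all libraries to 1 depth was chosen after seeing the data, and the other settings before. Of 117 results for the genes named in the report, 65 passed the threshold. Of these 65, 30 also passed under every setting other than leaving out a library, and 34 with every library left out in turn. Among results that passed in the main fit or under another setting, 0 changed sign between them. Sign changes of results that passed in neither were not counted. The size factors, the stricter filter, thinning, the replicate block and the fit to only the 6 libraries compared gave 1558 to 2040 genes for 32 against 26 °C, 7 to 10 for 29 against 26 °C and 141 to 191 for 32 against 29 °C. RLE gave 2029, 10 and 171 genes for 32 against 26, 29 against 26 and 32 against 29 °C, and thinning 1880, 9 and 191. DESeq2, no filter and limma on FPKM moved the counts. In the same order DESeq2 gave 3109, 187 and 1171 genes, no filter 4043, 911 and 2490, limma on log2(FPKM + 1) 507, 2 and 33, and limma on log2(FPKM + 0.1) 438, 0 and 21. Limma on FPKM changed both the tool and the unit, so neither can be singled out, and the cause was not tested. On simulated counts limma on log2(CPM + 1) made 142 calls for 32 against 26 °C, against 145 with edgeR, but FPKM was not simulated. DESeq2 gave 18 and no filter 19 named results a call that filtered edgeR with all 9 libraries did not make. DESeq2 also made more false calls than edgeR on simulated counts. A 2-fold minimum left 1133 of the 2003 genes, by construction. Planned set tests with camera, with preset or estimated correlation, were not run because names exist only for genes the authors called.

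Leaving out 1 library gave between 711 (without replicate 2 at 26 °C) and 2163 (without replicate 1 at 29 °C) genes for 32 against 26 °C, between 1 (without replicate 3 at 29 °C) and 12 (without replicate 1 at 26 °C) for 29 against 26 °C, and between 28 (without replicate 2 at 29 °C) and 701 (without replicate 1 at 29 °C) for 32 against 29 °C. The list counts, 27, 1 and 10 with all libraries, ranged from 15 to 28, from 0 to 1 and from 3 to 12. The 10 fell to 3 without replicate 2 or 3 at 29 °C or replicate 3 at 32 °C and to 4 without replicate 2 at 32 °C. The 1, JARID2, was lost without replicate 2 at 26 °C and replicates 2 and 3 at 29 °C. Fewer libraries leave fewer degrees of freedom, yet without replicate 1 at 29 °C, the library nearest to 32 °C on the first component, more genes passed.

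The replicate block gave 1558, 7 and 141 genes, list counts of 26, 1 and 8, and 735 of the authors' calls. Libraries with the same number did not deviate together over all genes (correlations of -0.05 to 0.06 over 9 pairs, against -0.12 to 0.07 over 18 other pairs). No pairing by number was seen, though a link that touches few genes is not excluded. The block ended the calls of the USP6 N-terminal-like gene (0.0627) and TRPM8 (0.0505) at 32 against 26 °C, PLA2G7 (0.0587) at 29 against 26 °C, and LHX9 (0.0534) and HSP90AA1 (0.0621) at 32 against 29 °C, and no other named call. The fit to 6 libraries ended those of HBAA (0.0576) and SLC4A1 (0.0504) at 32 against 26 °C, and LHX9 (0.0532), HSP90AA1 (0.0724) and KDM6B (0.0508) at 32 against 29 °C. Summing the assembled genes of a symbol changed no list count. Of the authors' 1011 calls, DESeq2 recovered 860 and the fit to 6 libraries 851. The share of genes with 29 °C between the other temperatures was 89.6% with either scaling. Depth limits genes such as DMRT1, with 12 counts over the 32 °C libraries.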

Other observations

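The genes in the next paragraph were chosen after their values were seen, and so were the tests of gonad share, blood, steps between temperatures, sets of libraries, the other settings for those genes and the splits fitted to 6 libraries alone. The tests of other splits, of a single deviating library, of depth and of split genes were set before, although the last was read as undecided only once its result was seen. The limits for the blood test and for the steps of AMH and JARID2 were reworded after their results.

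Several abundant or metabolic genes outside the lists differed between 32 and 26 °C. UGT1A1, a glucuronosyltransferase, rose by 1.85 ± 0.33 on the log2 scale (edgeR adjusted p = 0.0119), from 10.4 ± 4.24 to 37.4 ± 10.1 CPM. GATM, which makes the precursor of creatine, rose by 1.60 ± 0.30, PCK1, an enzyme of glucose synthesis, by 1.39 ± 0.24 in 1 of its assembled genes and 0.90 ± 0.17 in another, and the sulfate transporter SLC13A1 by 0.83 ± 0.17. ACSM2A and FMO4, enzymes of acid and amine metabolism, rose by 1.31 ± 0.27 and 0.94 ± 0.12. APOE, a lipid carrier, had log2 fold changes of -0.96 and -1.19 in its 2 assembled genes, the first falling from 1886 ± 160 to 970.6 ± 83.7 CPM (edgeR adjusted p = 0.0138), and PLTP, a phospholipid transfer protein, fell by 1.11 with an SE of 0.14. The complement genes C1QA and C1QB fell by 1.36 and 1.42 (SE 0.26 and 0.28), and IFIH1 and IRF3, which act in the response to viral RNA, fell by 0.85 and 0.88 (SE 0.11 and 0.14). FSHR, the receptor of follicle-stimulating hormone, fell by 1.64 with an SE of 0.33 (edgeR adjusted p = 0.0206). Under the other settings 0 of the 17 assembled genes named here, 2 of hemoglobin subunit pi included, reversed, and 7 kept their call under each: c260192_g1 of PCK1, c252796_g2 of APOE, FMO4, PLTP, IFIH1 and both of pi. The other 10 lost it with both limma fits on FPKM, with adjusted p up to 0.0581 for UGT1A1, 0.062 for GATM, 0.0549 for PCK1, 0.0784 for SLC13A1, 0.0767 for ACSM2A, 0.0752 for APOE, 0.0735 for C1QA, 0.072 for C1QB, 0.107 for IRF3 and 0.0618 for FSHR. Without replicate 1 at 26 °C, UGT1A1 (0.0509), GATM (0.0602), PCK1 (0.0675), SLC13A1 (0.0673), ACSM2A (0.0589) and FSHR (0.0554) lost it, without replicate 2 GATM (0.06), SLC13A1 (0.071) and ACSM2A (0.0713), and without replicate 3 PCK1 (0.0641), SLC13A1 (0.0786), C1QA (0.0588), C1QB (0.0684) and FSHR (0.068). At 32 °C, leaving out replicate 1 ended the call of FSHR (0.058), replicate 2 those of GATM (0.0542), SLC13A1 (0.0775), C1QA (0.0562), C1QB (0.0521) and FSHR (0.0712), and replicate 3 those of SLC13A1 (0.0508) and ACSM2A (0.0649). No test was made of these genes as groups.

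For AMH the step from 29 to 32 °C exceeded that from 26 to 29 °C, with a difference of steps of -5.24 ± 0.43 on the log2 scale (edgeR adjusted p = 0.000857 over all genes). AMH was the 1 gene of 58462 to pass this test, and 4690 had an unadjusted p under 0.05, where chance alone gives a share of 0.05 of the genes tested. DMRT1, CLDN11, CRABP1 and INHA had differences of the same sign, -3.15 ± 0.53, -2.22 ± 0.38, -2.86 ± 0.50 and -3.29 ± 0.70. These did not pass (edgeR adjusted p from 0.184 to 0.306), so a larger second step is not shown to be particular to AMH. JARID2, which fell between 26 and 29 °C and stood level at 32 °C, had a difference of 1.11 ± 0.21 that did not pass (edgeR adjusted p = 0.271), so whether its steps differ stays open. Of the 4 assembled genes named KDM6B, c281448_g1, c282584_g4 and c282584_g1 had differences of -0.11 ± 0.37, -0.19 ± 0.37 and 0.06 ± 0.42, within 1 log2 unit of equal at 2 SE. The remaining gene, c277670_g1, had -0.43 ± 0.38, which reaches beyond that, so equal steps stay open for KDM6B.

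The first pattern weighed is the fall of AMH, DMRT1, INHA and CLDN11 at 32 against 26 °C, where a smaller share of gonad in the complexes would lower every gonadal transcript alike. Relative to the mean of NR5A1 and LHX9 in the same library, the 4 genes still fell, with a median log2 change of -2.7 and excesses of -4.78 ± 0.45, -2.73 ± 0.30, -2.67 ± 0.82 and -1.94 ± 0.38, which argues against share as the whole cause for these 4, of which INHA and CLDN11 were picked from the lowest changes and AMH and DMRT1 come from a fixed list. Of the other genes set against the same mean, FSHR (-0.64 ± 0.44) and HSD17B1 (0.27 ± 0.21) showed no excess beyond 2 SE, as a smaller share would give. Nor did the adrenal gene CYP21A2 (-0.5 ± 0.42). TGFBR3L (-2.02 ± 0.55) and KDM6B (-1.28 ± 0.27), both among the lowest changes, did show an excess. NR5A1 is also an adrenal gene, whose transcripts from outside the gonad could have hidden part of a loss. For 32 against 26 °C the highest edgeR adjusted p of the 4 genes over the 9 fits with a library left out was 0.0152. INHA and CLDN11 could be picked only if the libraries of these temperatures did not overlap. A call resting on 1 library would hardly enter that way, so for them the value decides nothing. For AMH and DMRT1, from the fixed list, the highest were 1e-04 and 0.00334, which argues against a single library there. The authors had called both on these libraries, however. For 32 against 29 °C INHA lost its call without replicate 3 at 29 °C (0.0544). For the smaller fall of NR5A1 and LHX9, whose changes differed by -0.11 ± 0.23, a smaller share of gonad cannot be told apart from lower expression. For NR5A1 neither can be told apart from a loss of its adrenal transcripts. A difference between male-biased and female-biased development, which this design cannot separate from temperature itself, stays open, as untested.

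The second pattern is that MTIF3, CXADR and NPDC1, among the highest named at 32 °C, were at least 8-fold higher in each of the same 4 libraries, replicate 3 at 29 °C and all of 32 °C, than in any of the other 5. Over all tested genes, 192 had such a gap of at least 8-fold, with at least 0.5 CPM in every library above it (the libraries called on here), 14 of them this set, which holds all of 32 °C, so an effect of temperature would also add to it. The presence of replicate 3 did not come with a general likeness to 32 °C: over 1996 other called genes its median gene lay 35.3% of the way from the 26 to the 32 °C mean, against 49.8% and 31.4% in replicates 1 and 2. Among sets of 3 to 6 libraries shared by at least 5 genes, another 24 genes lay in 3 sets that split the 26 or the 32 °C libraries, such as 12 genes on in replicate 3 at 26 °C and replicates 2 and 3 at 29 °C, and 5 genes in 1 set that follows temperature (with sets of any size, 67 genes in 8 sets split them), so sequences that some embryos or clutches carry and others lack are a candidate explanation, with no genotype tested here. Of 13 genes at 0 in all 26 °C libraries and higher at 32 °C, 76.9% passed after thinning, between the limits set for and against depth, and 0 had a partner of the same assembly component that was lower at 32 °C (0.2 in random sets, permutation p = 1), too few to tell whether variants split 1 gene into 2.

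The third pattern is the fall of red blood cell genes at 32 °C. At 29 against 26 °C the 4 listed genes showed no fall. Their log2 fold changes were 0.17 ± 0.13 for HEMGN, 0.40 ± 0.14 for HBAD, 0.36 ± 0.16 for HBAA and 0.23 ± 0.16 for SLC4A1. None of these passed over all genes. Less blood in the complexes would lower them alike, and HEMGN fell more than HBAD by a difference of -0.43 ± 0.17, within the limit of 0.81 that allows for picking the extremes of 4 genes, so for these genes less blood cannot be told apart from lower expression. Hemoglobin subunit pi (c263455_g2, 3486 bases, named by product) is an embryonic globin chosen after its values were seen. It fell from 1373 ± 165 CPM at 26 °C through 830.3 ± 102 at 29 °C to 394.9 ± 49.0 at 32 °C. Its log2 fold change at 29 against 26 °C was -0.73 ± 0.12 and did not pass (edgeR adjusted p = 0.113). At 32 against 26 °C it fell further than the mean of HBAA, HBAD and SLC4A1 in the same library, by -1.1 ± 0.17 on the log2 scale. Less blood that lowers all of them alike would not give such an excess. Since pi was chosen after its values were seen, the excess is no independent test, and less blood stays open. Reads shared between globin copies and a difference between male-biased and female-biased development stay open, as untested. Temperature and sex bias change together in this design and cannot be told apart.

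Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05. Every other split mixes the temperatures compared, so a real difference would enter the spread within its groups and lower its count. The low counts of the other splits are therefore no separate evidence. With all 9 libraries in the model, 1 of the 10 splits, the real one, gave as many genes in each: 2003 against at most 7 in another split for 32 against 26 °C, 9 against at most 8 for 29 against 26 °C, and 169 against at most 2 for 32 against 29 °C. The 8 came from the split that put replicate 1 at 29 °C with replicates 1 and 2 at 26 °C. Fitted to the 6 libraries alone, 29 against 26 °C gave 7 genes in the real split and also 7 in that same other split, so 2 of the 10 gave as many. In that form the values were 1825 against at most 5 for 32 against 26 °C and 169 against at most 4 for 32 against 29 °C.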
